A study of Mus musculus with 36 samples.

How the data were processed

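The series held 36 libraries of mouse heart, 3 for each combination of 2 genotypes and 6 times of day. Per the labels' protocols, mice were kept in a 12 h light and 12 h dark cycle on normal chow, hearts were flash frozen, RNA was extracted with Trizol, and libraries were made from total RNA with an Illumina TruSeq RNA kit. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program and the gene annotation are not given in the sources used here.

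For 33 libraries the authors deposited a table of 18762 NCBI Gene IDs with a value per gene, and the values fit FPKM (reads per kilobase of transcript and 1e6 reads): low values rise in steps that depend on the gene, and dividing deposited counts by the values gives the same gene length in every library tested. That unit was inferred from the values. The authors deposited expected counts, which need not be whole, in the 3 tables recorded for KO at ZT22. Of these values, zeros included, 10.5 to 10.8% were not whole. Per the file headers, however, these columns name the KO ZT10 libraries, and their values matched the FPKM of KO ZT10: zero and nonzero genes fell together for 99.957 to 99.963% of genes in the same-named pairs and for 92.4 to 92.9% in other pairs, and the SD of the log2 length implied per gene was 0.0142 to 0.0154 against 0.1455 to 0.1548. These counts were therefore used as those of KO ZT10, to recover lengths for 16632 genes, which the recovery of depth relies on, and in the edgeR alternative. KO at ZT22 was not analysed here. As a result the mean effect covers 5 times, no contrast was made at ZT22, the interaction has 4 contrasts, the dark phase in the light minus dark contrast is ZT14 and ZT18, and rhythms in KO-labelled hearts rest on 5 times. In the WT ZT14 tables the replicate numbers in the column headers differ from those of the recorded samples, and the record was followed. There was 1 further column of per-sample values, a repeat of KO ZT14 replicate 3 inside another library's table, which was not used.

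Of the IDs, 18623 were given symbols and coordinates from the RefSeq annotation of the same assembly as mm10, 139 were not named, and 0 of the named genes were mitochondrially encoded, so the share of mitochondrial reads could not be checked. Depth was recovered from the steps of low FPKM values, using 272 to 402 genes per library, of whose values 66.6 to 78.4% lay within 0.15 of a whole read. It came to 15.02 to 17.38 M reads (M, 1e6) in KO-labelled libraries (mean 15.9 ± 0.67 SD, n = 15) and 13.67 to 15.73 M in WT libraries (14.6 ± 0.66, n = 18), and differed from the 3 deposited count totals by -0.33 to 0.28%. Gene lengths were computed from those totals, so that agreement follows from the method and does not test the depth of the other libraries. Counting error at such depth is small for genes above a few FPKM and large for genes near 0. No pair of libraries held identical values (0 pairs). Correlations of log2 values were 0.9893 to 0.9972 within groups and 0.974 to 0.9939 between groups, and the chi-square per degree of freedom of replicate pairs, on rebuilt counts, was 2.27 to 14.54 over 33 pairs, above sampling noise in each.

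Because FPKM are not counts, genes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend on mean level) on log2(FPKM + 1), with values scaled as deposited. The 11790 genes with at least 1 FPKM in at least 3 libraries entered the fit, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. A model of 11 group means (22 residual degrees of freedom) gave the mean KO minus WT effect over 5 times, the contrast at each time, the light minus dark contrast and the F test of the interaction, with all libraries sharing the estimate of spread. A model with a cosine and a sine of 24 h period per genotype (27 residual degrees of freedom) gave the rhythm in each genotype, its amplitude and peak, and the test of the difference. Fold changes are on the log2(FPKM + 1) scale, which understates those of low genes.

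The design, the alternatives and 37 gene lists were fixed before the data were examined, except where an alternative is named as added later. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists with at least 3 measured genes, meaning genes past the FPKM filter. For the mean effect 4 lists were called upward and 7 downward at that setting. Camera was run again with a correlation estimated per list and then called 0 lists (lowest adjusted p = 0.0656, 10 lists at an unadjusted p under 0.05). By fry 24 lists were called. Members were counted after adjustment over all genes and over the list alone. Genes are named by a rule set in advance: the 10 largest increases and decreases in the mean effect among genes of at least 1 FPKM on average with the same sign at every time, the 3 largest each way at every time, the 8 with the smallest adjusted p for the interaction and the rhythm difference, the 8 largest amplitudes in each genotype, up to 4 members of each list by adjusted p, and all clock genes of the lists. Predicted gene models were counted but not named, and some genes the rule names are not reported here. All 146 named genes past the threshold in the mean effect kept their direction under median-ratio scaling, quantile normalization, edgeR and removal of trends on length and GC content.

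The fits were tested on simulated counts for 16605 genes with 200 changed genes. In the mean effect 81.6% of genes changed 1.25-fold and 100% of those changed 1.5-fold were called, with 12 calls among the unchanged genes of 11625 tested. At ZT2 the shares were 6.2, 69.4, 94 and 100% for 1.25-, 1.5-, 2- and 4-fold changes, with 9 such calls among 11610. For the interaction they were 0, 18.4, 92 and 100% (8 among 11618), and for light minus dark 12.2, 79.6, 100 and 100% (4 among 11613). Rhythms of 1.25-fold amplitude were recovered for 87.8% of genes in WT (12 among 11620) and 63.3% in KO (5 among 11611), and differences of rhythm for 42.9% at 1.25-fold and 91.8% at 1.5-fold (8 among 11620). A list raised 1.25-fold, fatty acid oxidation, was called with camera adjusted p = 3.35e-108. Of the 34 lists 1 other was called, not counting the list of PPAR-responsive lipid genes. Genes were simulated independently at a dispersion of 0.01, whereas the real fatty acid oxidation list had an estimated correlation of 0.427. The simulation therefore does not test calls on lists of correlated genes.

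Alternatives fixed in advance were other scalings, other filters, a pseudocount of 0.1, limma without the trend, library weights, blocks of replicate number, each library left out in turn, fits on subsets, time as a factor, stricter thresholds, an estimated correlation and fry. Added after the data were seen were edgeR 4.0.16 on counts rebuilt from FPKM (deposited counts for the 3 KO ZT10 libraries), thinning of every library to 13.67 M reads, removal of trends on gene length and GC content (98.9% of tested genes had both), a block with the header numbers, and rhythms without single times. DESeq2 and its size factors, meant for deposited counts, were not run. Python steps used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.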

Results

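Transcript levels were measured by RNA sequencing of mouse hearts collected every 4 h around a 12 h light and 12 h dark cycle, at zeitgeber times (ZT, hours after lights on) 2, 6, 10, 14, 18 and 22. The animals were C57BL/6 mice 8 weeks old that carried a floxed Rev-erb allele (labelled WT) or that allele together with an MHC transgene (labelled KO). MHC in such strains usually stands for a myosin heavy chain promoter that drives Cre recombinase in heart muscle cells, a design that asks what the nuclear receptor Rev-erb, a transcriptional repressor of the circadian clock, does in the heart over the day. No group carried the MHC transgene alone, so its own effect cannot be told apart from that of Rev-erb loss. Each of the 11 groups analysed held 3 libraries, which gave 18 WT libraries at 6 times and 15 KO libraries at 5 times. The 3 tables recorded for KO at ZT22 held counts of the KO ZT10 libraries, so KO at ZT22 was not analysed here. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure the spread between these samples, and whether that spread is between animals is not known. Depth recovered from the FPKM values was 15.02 to 17.38 M reads (M, 1e6) per KO library and 13.67 to 15.73 M reads per WT library.

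The Rev-erb genes Nr1d1 and Nr1d2 were examined in every library before any comparison. Nr1d1, which encodes Rev-erbα (NCBI Gene 217166, chromosome 11, 98767932 to 98775377, mm10), was higher, not lower, in all 15 KO-labelled libraries, at 192 to 317 FPKM against 9.29 to 87.7 FPKM in the 18 WT libraries. Its mean over the 5 shared times was 236 FPKM in KO-labelled and 41.3 FPKM in WT libraries (log2 difference 2.75 ± 0.07 SE, n = 15 per genotype, limma adjusted p = 1.83e-22). Nr1d2, which encodes Rev-erbβ (NCBI Gene 353187, chromosome 14, 18204056 to 18239106), ranged from 22.4 to 35.4 FPKM in KO-labelled libraries and from 10.7 to 42.4 FPKM in WT libraries. The labels do not say which exons or which of the 2 genes were removed, and the tables give a single value per gene, so these values do not test the deletion and libraries are called KO-labelled throughout. The annotated span of Nr1d1 overlaps that of Thra on the opposite strand, and the labels name no stranded protocol, so reads of the shared stretch cannot be told apart. Thra, named here for that overlap and outside the rule for named genes, fell from 34.3 to 18.4 FPKM (adjusted p = 3.47e-20).

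Averaged over the 5 times, KO-labelled hearts held more transcripts of the stress genes Sprr1a and Nppa, the kinase inhibitor gene Cdkn1a and the clock gene Arntl, and fewer of the metabolic enzyme genes Ces1d, Nampt and Fbp2. The increase was largest for Sprr1a (NCBI Gene 20753, chromosome 3, 92483954 to 92485881), a cornified envelope protein that stressed heart muscle cells also make, which went from 0.295 to 16.1 FPKM (log2 difference 3.60 ± 0.16 SE, n = 15 per genotype, limma adjusted p = 4.03e-17). Nppa (NCBI Gene 230899, chromosome 4, 148000722 to 148002074), the precursor of atrial natriuretic peptide, rose from 286 to 2819 FPKM (3.31 ± 0.10, adjusted p = 1.62e-21). Cdkn1a (NCBI Gene 12575, chromosome 17, 29090979 to 29100722), an inhibitor of cyclin-dependent kinases, rose from 22.6 to 187 FPKM (3.30 ± 0.12, adjusted p = 2.24e-19). The deepest decrease was that of Ces1d (NCBI Gene 104158, chromosome 8, 93166072 to 93197804), a carboxylesterase that hydrolyses triglycerides, which went from 70.4 to 3.88 FPKM (log2 difference -3.87 ± 0.06, adjusted p = 2.94e-26).

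Further increases were seen for Slc41a3, of a family of magnesium transporters, from 26.7 to 204 FPKM (3.10 ± 0.06, adjusted p = 4.74e-25), and for Kcne1, a regulatory subunit of a cardiac potassium channel, from 2.38 to 19.4 FPKM (2.60 ± 0.07, adjusted p = 1.83e-22). Mrln, which encodes the micropeptide myoregulin that restrains the calcium pump of the sarcoplasmic reticulum, rose from 0.787 to 9.51 FPKM, and Slc17a7, a vesicular glutamate transporter, rose from 5.21 to 23.8 FPKM. Their log2 differences were 2.54 ± 0.13 and 1.98 ± 0.07. Myot (NCBI Gene 58916, chromosome 18, 44334053 to 44355740), which encodes the Z-disc protein myotilin, fell from 34.3 to 2.33 FPKM (-3.38 ± 0.08, adjusted p = 5.96e-23). Nampt (NCBI Gene 59027, chromosome 12, 32820335 to 32853369), the rate-limiting enzyme of NAD salvage, fell from 74.7 to 16.1 FPKM (-2.14 ± 0.04, adjusted p = 1.56e-25). Ttll1, a tubulin polyglutamylase subunit, and Fah, the last enzyme of tyrosine breakdown, both had a log2 difference of -1.98, with SEs of 0.04 and 0.05. Among enzymes of sugar metabolism, Fbp2 fell from 31.4 to 8.31 FPKM and Pfkfb1 from 5.54 to 0.850 FPKM, with log2 differences of -1.83 ± 0.07 and -1.79 ± 0.08. Scn4b, a sodium channel subunit, fell from 8.92 to 1.90 FPKM (-1.79 ± 0.10), and Masp1, a protease of the lectin complement pathway, from 8.67 to 1.97 FPKM (-1.69 ± 0.08). The rule chose these genes among those with the same sign at all 5 times, and the log2(FPKM + 1) scale understates the change of the low ones, such as Sprr1a.

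**Figure D1:**
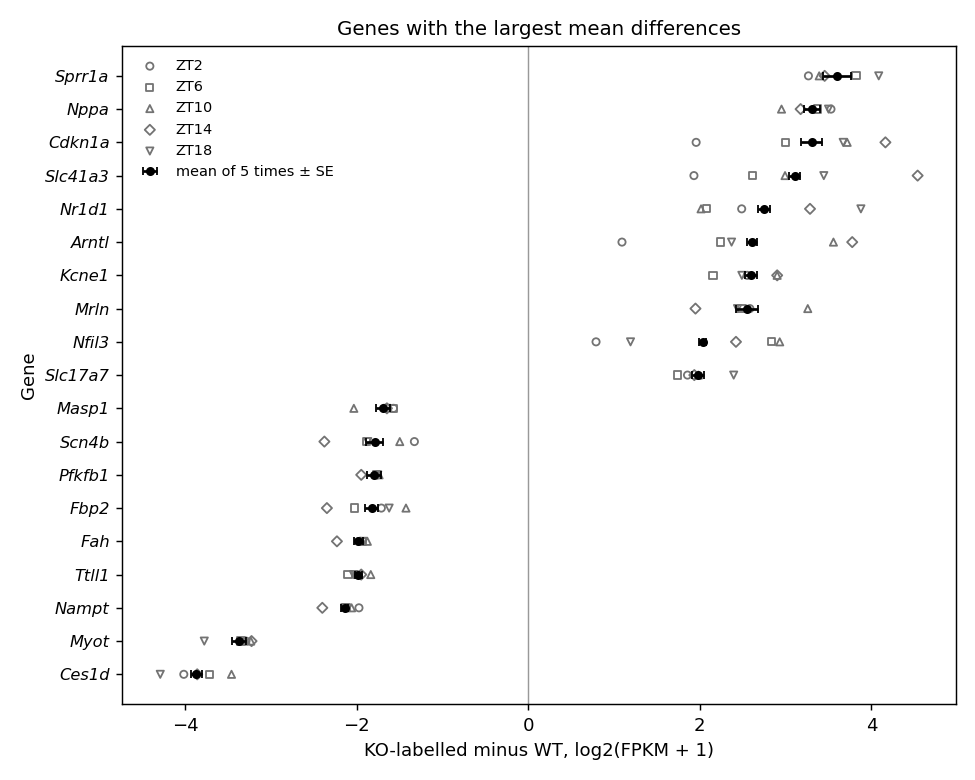
Genes named for the largest increases and decreases in KO-labelled libraries. The x axis is the KO-labelled minus WT difference on the log2(FPKM + 1) scale, open symbols are the 5 times (3 libraries per genotype each) and black points are the mean over the times with its SE. Values run from -3.87 for Ces1d to 3.60 for Sprr1a.

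Of 11790 genes tested with limma, 6679 passed the adjusted threshold of 0.05 in the mean effect, 3916 higher and 2763 lower in KO-labelled libraries, and 128 of them had a log2 difference of at least 1 in size (73 higher, 55 lower). The excess of higher genes depended on the scaling. Higher and lower genes were 3349 and 3341 with median-ratio scaling, 3300 and 3398 with quantile normalization, 3562 and 3552 by edgeR on rebuilt counts, and 3368 and 3326 with trends on gene length and GC content removed. Of the 6679 genes, 5108 had the same sign at all 5 times. The first principal component held 36.3% of the variance and separated the genotypes, and KO-labelled libraries were deeper than WT libraries by 1.3 M reads on average (two-sided permutation p = 4e-05, 100000 resamples). The labels name no batch, so the genotype difference could not be recomputed within batches. In WT at ZT2, replicate 1 stood apart from the other replicates in stress genes, with 114 FPKM of Hspa1a against 28.9 and 26.9 FPKM, and without it the count was 6792 genes (3941 higher, 2851 lower).

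Most clock genes whose promoters hold Rev-erb response elements (RORE-driven) were raised in KO-labelled hearts at all 5 times. Of the 6 measured members 5 rose and 1 fell (5 and 1 adjusted over the list alone), with a median log2 difference of 1.32 (camera adjusted p = 5.77e-04, adjusted p = 0.0656 with an estimated correlation). Arntl (NCBI Gene 11865, chromosome 7, 113178471 to 113314126), which encodes the clock activator BMAL1, rose from 5.10 to 27.8 FPKM (2.61 ± 0.06, adjusted p = 3.32e-23). Nfil3 (NCBI Gene 18030, chromosome 13, 52967209 to 52982878), a transcriptional repressor, rose from 12.4 to 42.3 FPKM (2.03 ± 0.04, adjusted p = 1.44e-24). The BMAL1 partner genes Npas2 and Clock rose by 1.78 ± 0.05 and 0.62 ± 0.03 on the log2 scale, and the repressor Cry1 rose by 0.86 ± 0.03.

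Clock genes driven through E-boxes were also higher: 7 of 10 rose, 0 fell and 3 were not called (7 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 6.69e-04, adjusted p = 0.0656 with an estimated correlation). Dbp, a transcription factor of clock output, rose from 53.02 to 116 FPKM (1.65 ± 0.05, limma adjusted p = 2.16e-20). Ciart, a repressor of the clock, rose from 7.09 to 23.5 FPKM (1.90 ± 0.08, adjusted p = 2.71e-17). Smaller increases were those of Hlf (0.73 ± 0.04), Bhlhe41 (0.46 ± 0.04), Cry2 (0.33 ± 0.03), Tef (0.23 ± 0.03) and Bhlhe40 (0.17 ± 0.04). The period genes Per1, Per2 and Per3 were not called, with differences of 0.12 ± 0.07, 0.10 ± 0.08 and 0.02 ± 0.04.

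**Figure D2:**
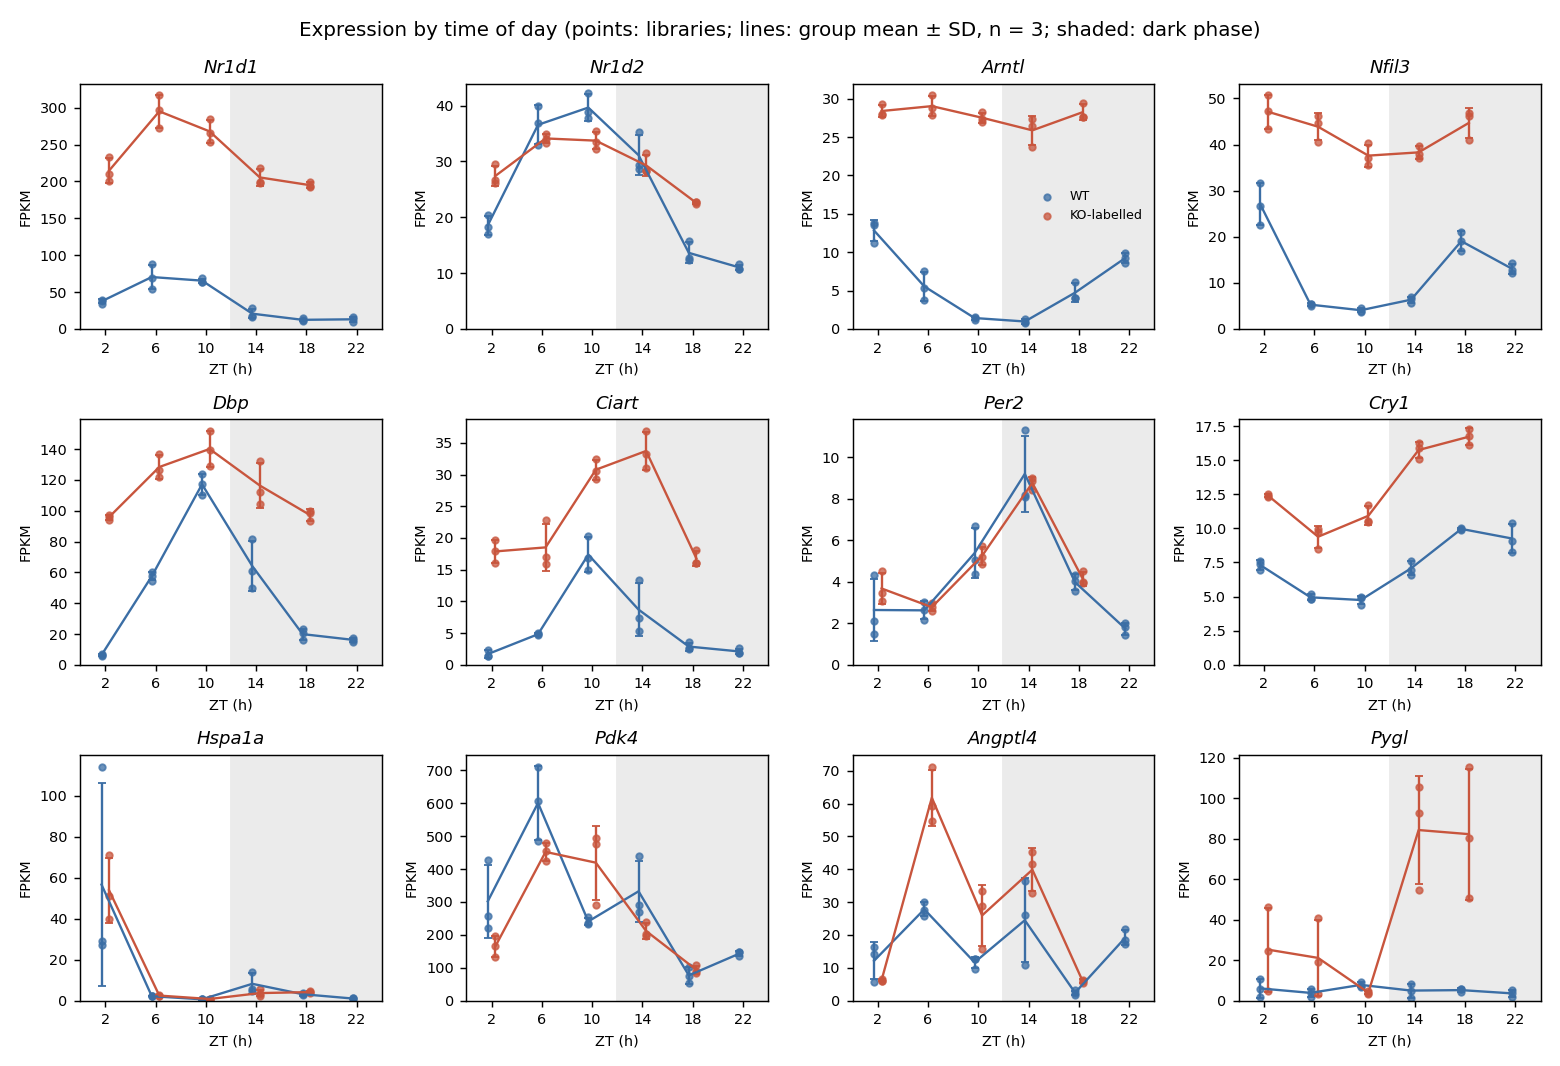
FPKM of 12 genes by time of day. The x axis is ZT in hours, points are libraries, lines join group means with SD (n = 3), and the shaded stretch is the dark phase; KO-labelled libraries have no values at ZT22. Nr1d1, Arntl, Nfil3, Dbp and Cry1 lie higher in KO-labelled than in WT libraries, and Per2 follows nearly the same course in both.

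Genes of fatty acid use were lower in KO-labelled hearts. Of 20 genes of fatty acid oxidation 17 fell, 2 rose and 1 was not called (the same counts adjusted over the list alone), with a median log2 difference of -0.25 (camera adjusted p = 1.72e-09, adjusted p = 0.113 with an estimated correlation). Examples were Eci2, a peroxisomal and mitochondrial isomerase of unsaturated fatty acids, from 147 to 101 FPKM (-0.54 ± 0.02, limma adjusted p = 1.9e-17), Acsl1, which activates long-chain fatty acids, from 413 to 306 FPKM (-0.43 ± 0.02), and the carnitine carrier Slc25a20 from 159 to 124 FPKM (-0.36 ± 0.02). Of 14 PPAR-responsive lipid genes 12 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.30 (camera adjusted p = 8.73e-06, adjusted p = 0.133 with an estimated correlation). Acot1, an acyl-CoA thioesterase, fell from 19.4 to 8.78 FPKM (-1.05 ± 0.06) and the fatty acid transporter Cd36 from 780 to 617 FPKM (-0.33 ± 0.02). The member that rose was Angptl4, an inhibitor of lipoprotein lipase, from 15.7 to 28.0 FPKM (0.65 ± 0.14, adjusted p = 1.52e-04).

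Triglyceride turnover genes changed in both directions, most of them downward. Of 16 lipid droplet genes 11 fell and 4 rose (11 and 4 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 0.00233, adjusted p = 0.0656 with an estimated correlation). The synthesis enzymes Dgat2 and Gpam fell by 0.79 ± 0.03 and 0.71 ± 0.04 on the log2 scale, and the droplet coat gene Plin3 fell by 0.64 ± 0.03. Pnpla2, the main triglyceride lipase of the heart, rose from 256 to 395 FPKM (0.62 ± 0.02, limma adjusted p = 1.4e-18). Breakdown of branched-chain amino acids was lower for 13 of 18 genes and higher for 3 (14 and 3 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 8.73e-06, adjusted p = 0.0656 with an estimated correlation). Bckdhb and Dbt, subunits of the branched-chain ketoacid dehydrogenase, fell from 45.6 to 26.9 and from 28.6 to 17.2 FPKM. Of 12 regulators of mitochondrial metabolism 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.17 (camera adjusted p = 0.00135, adjusted p = 0.0656 with an estimated correlation). Among them were the coactivator Ppargc1a (-0.50 ± 0.05), the muscle regulator Perm1 (-0.52 ± 0.02) and the nuclear receptor Ppara (-0.36 ± 0.03). In the citric acid cycle 9 of 18 fell and 2 rose (9 and 2 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.00826, adjusted p = 0.349 with an estimated correlation). Idh2 fell from 1387 to 887 FPKM, while Mdh2 rose from 1259 to 1460 FPKM. In that list 12 fell with median-ratio scaling (median -0.08), 13 with quantile normalization (-0.13) and 11 with length and GC trends removed (-0.10), with 2 higher in each.

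Lists of glucose use and the respiratory chain were not called as groups at the preset settings, but some were under others. Glucose uptake and glycolysis had camera adjusted p = 0.016 without a filter, 0.0331 with a mean of at least 5 FPKM and 0.0488 without WT ZT2 replicate 2. Pyruvate entry had 0.0407 with quantile normalization, 0.0409 without a filter and 0.0331 with a mean of at least 5 FPKM. Oxidative phosphorylation had 0.00205, downward, with trends on gene length and GC content removed. Of 21 genes of glucose uptake and glycolysis 13 rose and 4 fell (13 and 4 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 0.0707). Pfkp, a phosphofructokinase isoform, rose from 25.8 to 57.3 FPKM (1.12 ± 0.04, limma adjusted p = 7.6e-20), Hk1 from 66.4 to 101 FPKM and Pgk1 from 250 to 353 FPKM. Glycogen genes split into 5 higher and 7 lower of 17 (6 and 7 adjusted over the list alone, camera adjusted p = 0.327), with a median of -0.01 and a mean of 0.05, so that median and mean differed in sign and the test pointed down. Gys1, muscle glycogen synthase, fell from 58.0 to 38.1 FPKM and Gyg, glycogenin, rose from 131 to 178 FPKM. Of 13 genes of pyruvate entry into mitochondria 7 fell and 3 rose (7 and 4 adjusted over the list alone, camera adjusted p = 0.0921); the kinases Pdk1 and Pdk2 fell by 0.40 ± 0.02 and 0.30 ± 0.02, and Pdk3 rose by 0.60 ± 0.05. Oxidative phosphorylation had 14 higher and 12 lower of 36 (14 and 13 adjusted over the list alone, camera adjusted p = 0.312), with a median of -0.01 and a mean of 0.001. The split of that list went to 9 higher and 17 lower with median-ratio scaling, to 6 and 20 with quantile normalization, to 9 and 16 by edgeR and to 5 and 22 with trends on gene length and GC content removed. Ketone body use had 3 of 6 lower and 0 higher (the same adjusted over the list alone, camera adjusted p = 0.302), with Acat1 lower by log2 -0.21 ± 0.02.

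Stress and matrix genes were higher in KO-labelled hearts. Of 12 cardiac stress and fetal genes 9 rose and 0 fell (9 and 1 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 3.03e-04, adjusted p = 0.0702 with an estimated correlation). Nppa is also 1 of 4 measured atrial markers, a list that was not called (camera adjusted p = 0.374), with Myl4 at 0.29 ± 0.10, Dkk3 at 0.13 ± 0.05 and Stard10 at -0.19 ± 0.03. The other atrial markers of that list, Myl7, Sln and Bmp10, did not pass the FPKM filter. Besides Nppa, Nppb, the precursor of brain natriuretic peptide, rose from 402 to 961 FPKM (1.39 ± 0.08, limma adjusted p = 4e-15), Rcan1, a calcineurin inhibitor, from 56.5 to 110 FPKM (0.98 ± 0.05) and Gdf15, a stress-induced cytokine, from 1.502 to 7.14 FPKM (1.54 ± 0.10). Of 20 extracellular matrix and fibrosis genes 18 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 8.73e-06, adjusted p = 0.133 with an estimated correlation). The basement membrane collagens Col4a1 and Col4a2 rose from 76.6 to 126 and from 58.7 to 87.7 FPKM, the growth factor gene Tgfb2 from 3.14 to 4.94 FPKM and Ccn2, connective tissue growth factor, from 37.0 to 61.7 FPKM. Fibroblast markers moved along with these genes: 5 of 9 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.327), led by Mfap5 (0.39 ± 0.06) and Lum (0.24 ± 0.05), and with median-ratio scaling 3 rose and 1 fell.

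Genes of electrical and contractile function changed in both directions. Of 21 ion channel genes of the action potential 11 fell and 6 rose (11 and 6 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.009, adjusted p = 0.0702 with an estimated correlation). The pacemaker channel genes Hcn2 and Hcn4 fell from 12.3 to 3.22 FPKM (-1.65 ± 0.05) and from 2.42 to 0.592 FPKM (-1.09 ± 0.05), and Cacnb2, a calcium channel subunit, fell from 27.5 to 18.3 FPKM. Calcium handling genes were 4 higher and 6 lower of 13 (the same adjusted over the list alone, camera adjusted p = 0.203). Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 4155 to 3043 FPKM (-0.45 ± 0.01, limma adjusted p = 3.7e-20) and its inhibitor Pln from 3957 to 3110 FPKM, while Casq2, calsequestrin, rose from 546 to 784 FPKM. In the sarcomere list 11 of 17 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.312), with Tcap, the Z-disc protein telethonin, up from 1282 to 2454 FPKM and Tnni3 and Myh6 down from 6700 to 4961 and from 5333 to 3981 FPKM. That split was 6 and 6 with quantile normalization and 6 and 5 with trends on gene length and GC content removed.

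**Figure D3:**
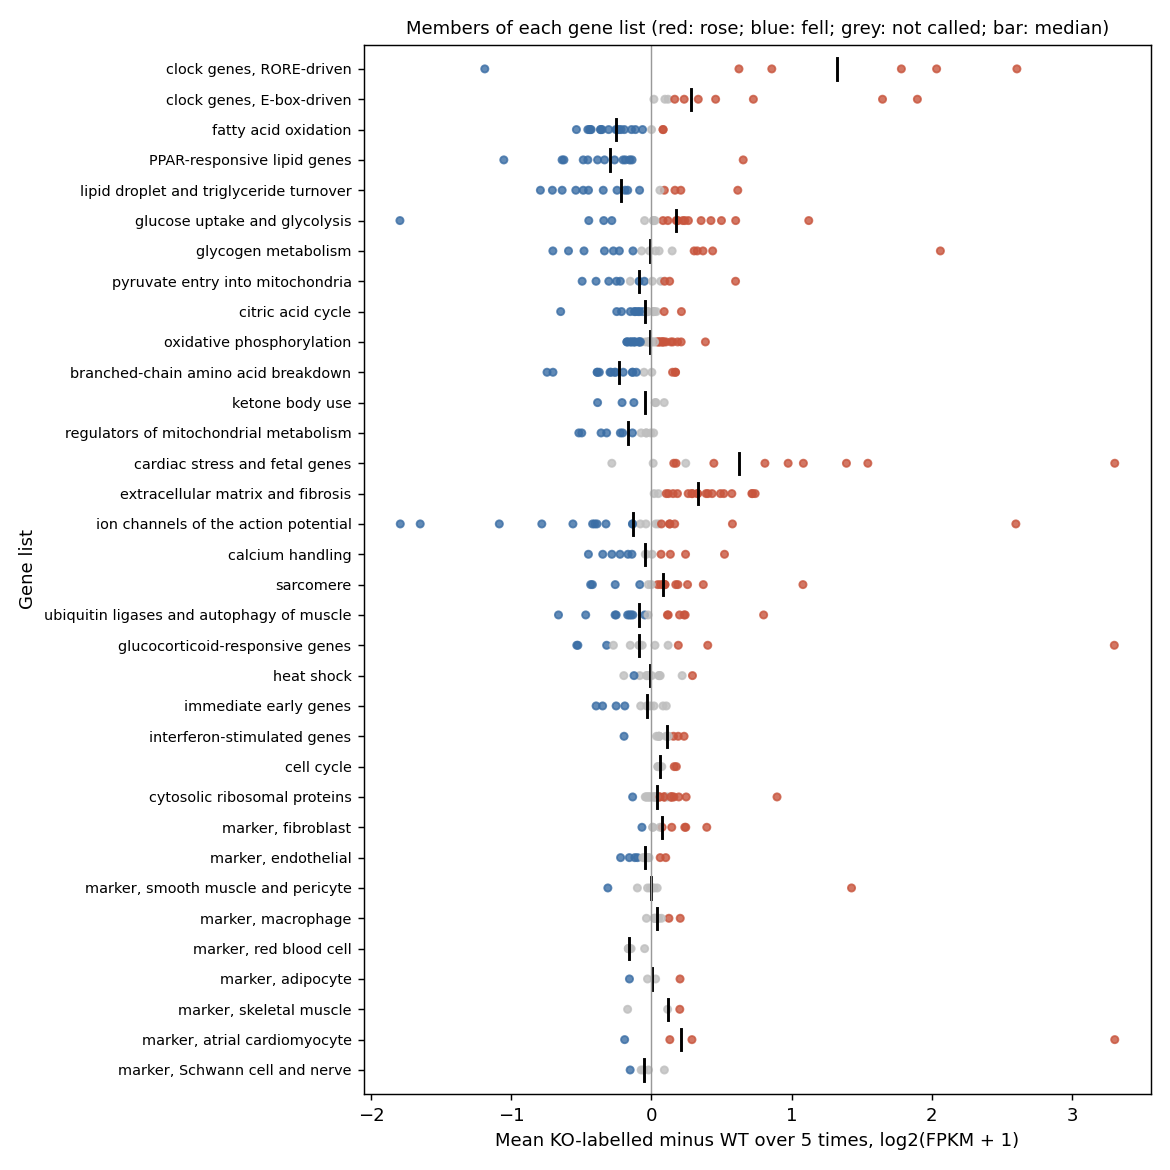
Mean KO-labelled minus WT difference over 5 times, on the log2(FPKM + 1) scale (x axis), for every measured member of 34 gene lists (y axis). Red points rose, blue points fell, grey points were not called, and black bars are medians; 17 of 20 fatty acid oxidation genes lie among those that fell and 18 of 20 matrix genes among those that rose.

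No call was made for the following lists at the preset settings; without a filter, cytosolic ribosomal proteins had a camera adjusted p of 0.0392. Ubiquitin ligases and autophagy genes were 6 higher and 9 lower of 16 (camera adjusted p = 0.302), with the lysosomal protease gene Ctsl up from 99.4 to 174 FPKM and Fbxo31 down from 31.5 to 19.5 FPKM. Glucocorticoid-responsive genes were 3 higher and 3 lower of 13 (adjusted p = 0.611); their median was -0.09, their mean 0.15, with Cdkn1a at 3.30, and the test pointed down. Of 12 heat shock genes 1 rose (Hspb1, 0.29 ± 0.07) and 1 fell (Hspd1, -0.12 ± 0.03), with a median of -0.009, a mean of 0.016 and an adjusted p of 0.799 for a downward test. Immediate early genes had 0 higher and 4 lower of 11 (adjusted p = 0.312), among them Ier3 and Egr1, and interferon-stimulated genes 3 higher and 1 lower of 12 (adjusted p = 0.543), with Ifit2 higher. By limma at single times, 10 of the 12 interferon-stimulated genes were higher and 0 lower at ZT6 (median 0.51). At ZT10, 0 were higher and 2 lower (median -0.13), and at ZT2, ZT14 and ZT18, 1, 1 and 0 were higher and 0 lower. Of 6 cell cycle genes 2 rose, Mcm3 and Ccna2 (adjusted p = 0.501). Cytosolic ribosomal protein genes were 14 higher and 1 lower of 30 (adjusted p = 0.126), with Rpl3 up from 144 to 269 FPKM (0.90 ± 0.03); their split was 11 and 6 with median-ratio scaling, 11 and 5 with quantile normalization or edgeR, and 8 higher against 11 lower once trends on gene length and GC content were removed, where their median of 0.04 turned to -0.01. The counts of higher and lower genes in the mean effect were the same when adjusted over the list alone.

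Markers of other cell types were not called as groups by camera at the preset settings either. By fry, which tests no contrast with other genes, endothelial (adjusted p = 0.00447), skeletal muscle (0.00375) and atrial markers (1.35e-11) were called. The other lists below were not called by fry. The adjusted p-values of lists below are those of camera. Endothelial markers were 2 higher and 4 lower of 11 (adjusted p = 0.203), with Pecam1 at -0.12 ± 0.02. Their split was 0 and 6 with median-ratio scaling, quantile normalization and edgeR, and 0 and 5 with length and GC trends removed. Macrophage markers were 2 higher and 0 lower of 10 (1 and 0 adjusted over the list alone, adjusted p = 0.773), with Cd68 at 0.21 ± 0.06. In the smooth muscle and pericyte list Acta2 rose from 95.9 to 245 FPKM and Abcc9 fell from 68.5 to 54.9 FPKM, with 6 of 8 not called (adjusted p = 0.773); the median was -0.001, the mean 0.13 and the test pointed down. Red blood cell markers had 0 calls of 6 in the mean by limma (adjusted p = 0.312). Of them 1 was lower with median-ratio scaling, 2 by edgeR, and 4 with quantile normalization (median -0.21) or with length and GC trends removed (median -0.23). Of 4 adipocyte markers Fasn rose and Cidea fell (adjusted p = 0.879, median 0.0008, mean 0.01, test down), and that median changed sign between scalings. Of 3 skeletal muscle markers Ckm, which heart muscle also expresses, rose (adjusted p = 0.598). Of 4 atrial markers Nppa, Myl4 and Dkk3 rose and Stard10 fell (adjusted p = 0.374), and of 5 Schwann cell markers 1 fell (adjusted p = 0.543). Apart from the macrophage list, the counts were the same adjusted over the list alone. Lymphocyte and neutrophil markers had 2 genes each past the FPKM filter and lung epithelium markers 0, so these lists were not tested. Among these genes Cd74 fell from 131 to 102 FPKM (-0.37 ± 0.08), and Ptprc, S100a8 and S100a9 were not called.

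At each time taken alone, Ces1d and Myot had the largest decreases among named genes of at least 1 FPKM on average, joined by Ttll1 at ZT2 and by Nampt from ZT6 to ZT18. At ZT2, 3529 genes differed (2196 higher, 1333 lower), led by Dbp, which was 95.9 ± 1.65 FPKM (SD, n = 3) in KO-labelled against 6.33 ± 0.534 FPKM in WT libraries (log2 difference 3.73 ± 0.12 SE, limma adjusted p = 9.48e-19), and by Nppa and Sprr1a. Fitted on the 6 libraries of ZT2 alone, the count was 2035. At ZT6, 3749 genes differed (2256 higher, 1493 lower), led by Sprr1a (3.82 ± 0.36), Eif3j2 and Nppa (3.37 ± 0.21). Eif3j2 has a close paralog with which it can share reads, and its libraries ranged from 0.260 to 21.2 FPKM in WT and from 0.420 to 19.0 FPKM in KO-labelled hearts, so its difference is uncertain. At ZT10, 3282 genes differed (1687 higher, 1595 lower), led by Cdkn1a, at 180 ± 29.4 against 12.7 ± 1.27 FPKM (3.72 ± 0.27, adjusted p = 1.13e-11), Arntl (3.56 ± 0.14) and Sprr1a (3.39 ± 0.36).

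At ZT14, early in the dark phase, 3645 genes differed (2259 higher, 1386 lower). Slc41a3 was 222 ± 15.2 FPKM in KO-labelled and 8.60 ± 0.843 FPKM in WT libraries (4.54 ± 0.14, limma adjusted p = 2e-19), Cdkn1a 227 ± 25.6 against 11.8 ± 1.90 FPKM, and Pygl, liver glycogen phosphorylase, 84.3 ± 26.6 against 4.97 ± 3.45 FPKM (3.98 ± 0.66, adjusted p = 2.79e-05). At ZT18, 3780 genes differed (2082 higher, 1698 lower), led by Sprr1a (4.09 ± 0.36), Nr1d1 (3.88 ± 0.16) and Pygl (3.68 ± 0.66). Over the 5 times 827 genes were higher and 600 lower at every time, 6918 differed at 1 or more times and 160 differed in opposite directions at different times. Red blood cell markers were higher for 5 of 6 genes at ZT2 (median log2 0.62) and lower for 6 of 6 at ZT6 (median -0.72) and for 3 of 6 at ZT18 (median -0.46).

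The split of higher and lower genes at single times depended on how libraries were scaled. With median-ratio scaling, KO minus WT at ZT2 gave 1719 higher and 1732 lower genes, KO minus WT at ZT6 gave 1772 and 1893, and KO minus WT at ZT14 gave 1687 and 1774. With quantile normalization the splits were 1689 and 1752, 1845 and 1910, and 1754 and 1746. These settings moved the median of all genes in the mean effect from 0.0215 to -0.0019 and -0.004 on the log2 scale.

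Whether the genotype difference changed over the day was tested with an interaction of genotype and time, which 633 of 11790 genes passed. Clock and clock output genes led: Dbp (limma adjusted p = 2.82e-13), Nfil3 (2.16e-12) and Arntl (1.63e-09). The Dbp difference was 3.73 ± 0.12 at ZT2 and 0.25 at ZT10, where WT itself reached 117 ± 6.78 FPKM. Arntl differed most at ZT14 (3.78), when WT libraries held 0.973 ± 0.316 FPKM against 25.9 ± 1.91 FPKM in KO-labelled libraries, and least at ZT2 (1.09), when WT libraries held 12.8 ± 1.41 FPKM. Nfil3 likewise differed by 2.93 at ZT10 and by 0.79 at ZT2, and Slc41a3 (9.63e-09) by 4.54 at ZT14 and by 1.93 at ZT2. Tcap (2.38e-08) was 567 ± 35.8 FPKM in WT at ZT2 against 2303 ± 83.3 FPKM in KO-labelled libraries, but 2075 ± 181 against 2663 ± 72.2 FPKM at ZT10. Ppp1r10, a phosphatase regulatory subunit (2.95e-07), was lower in KO-labelled libraries at ZT2 (-0.54) and higher at ZT18 (0.79), and Ptp4a1, a protein tyrosine phosphatase (4.94e-07), was lower at all 5 times, least at ZT2 (-0.30). Both genotype and interaction were past the threshold for 431 genes. The count rose to 964 without WT ZT2 replicate 1 and dropped to 411 without KO ZT18 replicate 3. It was 1418 with library weights and 225 with a replicate block within ZT.

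Between the light phase (ZT2, ZT6 and ZT10) and the dark phase (ZT14 and ZT18) the genotype difference changed for 118 genes. Of these, 47 had a larger and 71 a smaller KO minus WT value in the light. That split depended on the scaling: it was 55 and 63 with median-ratio scaling and 44 and 50 with quantile normalization. Slc41a3 had the value -1.48 ± 0.13 SE (limma adjusted p = 3.67e-08), Nr1d1 -1.39 ± 0.15 (2.47e-06), Arntl -0.78 ± 0.13 (0.0021), Cdkn1a -1.03 ± 0.24 (0.0342) and Pygl -2.95 ± 0.60 (0.0137). In the other direction, Dgat2, a triglyceride synthesis enzyme, had 0.37 ± 0.06 (0.00141), Nfil3 0.38 ± 0.09 (0.0287) and Tef 0.27 ± 0.06 (0.0171). Klf15, a metabolic regulator with a daily rhythm, was lower in KO-labelled libraries at ZT6 (-0.80) and higher at ZT18 (0.40), with a light minus dark value of -0.66 ± 0.12 (0.00601). Among the lists, oxidative phosphorylation (median 0.04, camera adjusted p = 0.00333, adjusted p = 0.609 with an estimated correlation) and endothelial markers (median 0.12, adjusted p = 0.029, adjusted p = 0.478 with an estimated correlation) were called upward. With quantile normalization neither was called and oxidative phosphorylation turned downward (adjusted p = 0.925). It was not called with length and GC trends removed either (0.952). Endothelial markers were also not called without KO ZT14 replicate 3 (0.0782), KO ZT18 replicate 1 (0.0535) or WT ZT2 replicate 1 (0.0638). Macrophage markers were called downward (median -0.19, adjusted p = 0.00333, adjusted p = 0.502 with an estimated correlation). Glucocorticoid-responsive genes (adjusted p = 0.054, downward) and ketone body use (0.0587, upward) were not called. Both passed without a filter (0.0379 and 0.0404), with a pseudocount of 0.1 (0.049 each), with a replicate block within ZT (0.036 each), with libraries thinned to equal depth (0.0442 each) and with length and GC trends removed (0.0375 and 0.038). Without WT ZT2 replicate 2 the glucocorticoid list had 0.00843. Lipid droplet genes passed with a replicate block within ZT (0.036) and E-box-driven clock genes with a pseudocount of 0.1 (0.049), and both with length and GC trends removed (0.038 each). Of single genes in the oxidative phosphorylation, endothelial and macrophage lists 1 passed the limma test, Pecam1 (0.20 ± 0.04, adjusted p = 0.00787). The gene count was 223 with library weights and 48 with a replicate block within ZT. It lay at 68 to 78 without KO ZT18 replicate 3 (68), KO ZT2 replicate 2 (73), KO ZT18 replicate 1 (75), WT ZT18 replicate 3 (75), WT ZT6 replicate 1 (76), KO ZT14 replicate 2 (77) or KO ZT14 replicate 3 (78).

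In WT hearts 4555 of 11790 genes fitted a 24 h cosine past the threshold, with 2752 peaks from ZT0 to ZT12 and 1803 from ZT12 to ZT24. Clock genes had the largest amplitudes (log2 scale, peak above mean, n = 18). Dbp had an amplitude of 1.76 ± 0.14 SE with a peak at ZT11.0 (limma adjusted p = 7.41e-10), Arntl 1.42 ± 0.07 at ZT0.5 (8.18e-16), Nr1d1 1.38 ± 0.07 at ZT7.1 (1.84e-14), Ciart 1.299 ± 0.12 at ZT11.0 and Nfil3 1.09 ± 0.12 at ZT22.3. The metabolic genes Ucp3, a mitochondrial uncoupling protein, and Pdk4, an inhibitor of pyruvate dehydrogenase, had amplitudes of 1.14 ± 0.16 at ZT8.6 and 1.12 ± 0.16 at ZT6.9, and Rtn4r, a receptor of neurite growth inhibitors, 1.12 ± 0.12 at ZT19.5. All 6 RORE-driven and all 10 E-box-driven clock genes were rhythmic in WT.

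In KO-labelled hearts 3172 genes were rhythmic, 2016 with peaks from ZT0 to ZT12 and 1156 from ZT12 to ZT24. How the genotypes compared depended on the setting. Fits on each genotype's own libraries gave 3706 genes in WT and 3510 in KO-labelled hearts, an amplitude of at least 0.25 left 681 and 762, and one of at least 0.5 left 91 and 105. Stress and metabolic genes, not clock genes, had the largest amplitudes (n = 15). Hspa1a and Hspa1b, inducible heat shock protein genes of near-identical sequence that can share reads, had amplitudes of 2.29 ± 0.56 and 2.11 ± 0.60 (limma adjusted p = 0.00859 and 0.0256). Pygl had 1.87 ± 0.38 at ZT19.1, Angptl4 1.78 ± 0.38 at ZT9.6, the immediate early genes Atf3 and Nr4a1 1.51 ± 0.26 and 1.38 ± 0.19, Gdf15 1.36 ± 0.15 and Pdk4 1.32 ± 0.19 at ZT8.4. Among KO-labelled libraries Pygl ranged from 4.71 to 46.2 FPKM at ZT2 and from 3.48 to 40.7 FPKM at ZT6, so its fitted curve is uncertain. At ZT14 and ZT18 all of them held 50.8 FPKM or more. Fitted peaks between ZT18 and ZT2, such as ZT23.5 for Hspa1a, ZT23.0 for Atf3 and Gdf15 and ZT0.0 for Nr4a1, lie where KO-labelled hearts have no values; in WT, Hspa1a was 56.6 ± 49.7 FPKM at ZT2 and 1.02 ± 0.148 FPKM at ZT22. Of the E-box-driven clock genes 7 of 10 were called rhythmic in KO-labelled hearts, and of the RORE-driven ones 2 of 6, Cry1 (0.40 ± 0.04 at ZT18.5) and Npas2 (0.26 ± 0.08 at ZT7.7).

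The rhythm itself differed between genotypes for 128 genes, 86 with a lower and 42 with a higher amplitude in KO-labelled hearts. Arntl had an amplitude of 1.42 ± 0.07 in WT and 0.06 ± 0.07 in KO-labelled hearts (limma adjusted p of the difference = 1.1e-09). Nr1d1 and Nr1d2 had 1.38 ± 0.07 against 0.32 ± 0.09 and 0.95 ± 0.04 against 0.33 ± 0.05 (1.25e-06 each). Slc41a3 went from 0.99 ± 0.09 to 0.27 ± 0.12 (1.8e-05), Tcap from 0.94 ± 0.05 to 0.24 ± 0.07 (1.72e-05), and Lmod2, a leiomodin of cardiac thin filaments, from 0.38 ± 0.03 with a peak at ZT6.8 to 0.20 ± 0.04 at ZT0.9 (4.29e-05). Pnpla3, a lipid droplet protein, gained amplitude, from 0.24 ± 0.05 with a peak at ZT21.4 to 0.56 ± 0.07 at ZT11.3 (2.87e-06), and the peak of Foxj2, a transcription factor, moved from ZT23.5 to ZT9.1 (1.72e-05). Other clock genes past this test were Dbp (0.00183), Npas2 (8.93e-04), Nfil3 (0.0435), Tef (0.0435), Bhlhe41 (0.045) and Per3 (0.0233), whereas Per2 (0.557), Per1 (0.631), Cry1 (0.0846), Clock (0.0865) and Ciart (0.091) did not pass. The list of fatty acid oxidation had 9 rhythmic members in WT and 2 in KO-labelled hearts, with 0 members past the test of the difference by limma.

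Most rhythmic genes were not shown to differ between genotypes. Both genotypes were rhythmic for 2060 genes, where 1225 would be shared if the calls were independent, and 85.4% of them had peaks within 3 h of each other (median KO minus WT shift -0.43 h, quartiles -1.74 and 0.71 h; median amplitudes 0.18 in KO-labelled and 0.17 in WT hearts). The 2495 genes called rhythmic in WT alone included 52 with a tested difference, and the 1112 called in KO-labelled hearts alone included 23. With WT limited to the 5 times of KO-labelled hearts, 4627 genes were rhythmic in WT and the difference was called for 79 genes. Taking time as a factor makes the test of the difference the interaction itself, with the same 633 genes. The difference count was 281 with library weights and 71 without ZT6. It was 214 without WT ZT2 replicate 1, 85 without KO ZT2 replicate 2, and 80, 85 and 82 without KO ZT18 replicates 1, 2 and 3.

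**Figure D4:**
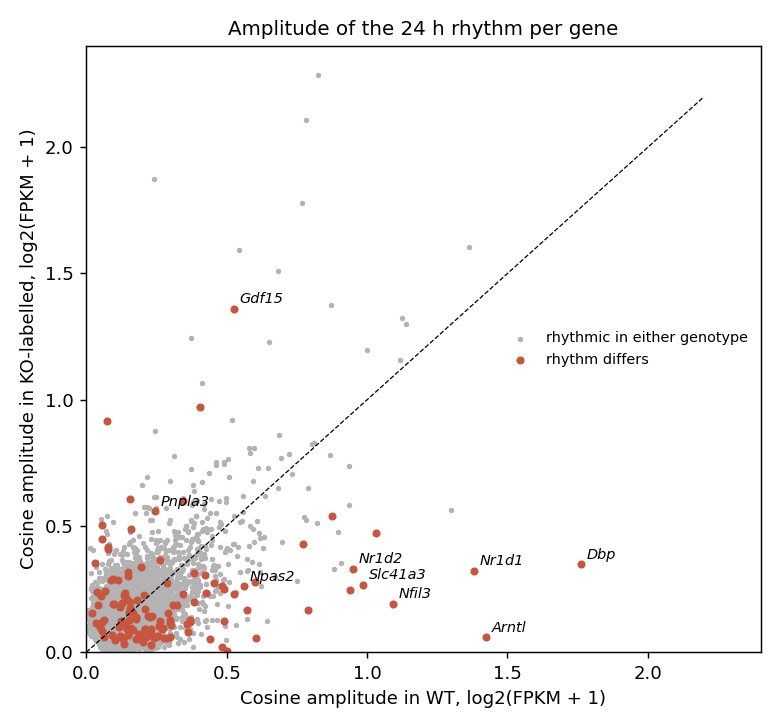
Amplitude of the 24 h cosine, on the log2(FPKM + 1) scale, in WT (x axis) and KO-labelled hearts (y axis). Grey points are genes rhythmic in either genotype, red points the 128 genes whose rhythm differs, and the dashed line marks equal amplitudes; Arntl and Nr1d1 lie far below it and Pnpla3 and Gdf15 above it.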

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

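The tests of depth, length and GC content, genotype labels, Thra reads, cell type markers and the rhythm of Nr1d1 below were chosen after the results were seen; the reassignments of labels were planned.

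Differences between times of day in the genotype effect were found for 633 genes by the interaction, for 118 genes by the light minus dark contrast and for 128 genes by the difference of rhythm (limma). For the interaction, adjusted p was 2.82e-13 for Dbp, 2.16e-12 for Nfil3, 1.63e-09 for Arntl, 9.63e-09 for Slc41a3, 2.38e-08 for Tcap, 2.95e-07 for Ppp1r10 and 4.94e-07 for Ptp4a1. It was 7.47e-06 for Nr1d2, 7.5e-06 for Nr1d1 and for Tef, 5.44e-05 for Bhlhe41, 7.23e-05 for Pnpla3, 0.000246 for Lmod2, 0.000346 for Foxj2, 0.000368 for Ciart, 0.000505 for Npas2 and 0.000638 for Per3. Larger values were 0.00324 for Clock, 0.00338 for Cdkn1a, 0.00688 for Gdf15, 0.00807 for Pdk4, 0.00898 for Pygl, 0.0105 for Hlf, 0.0143 for Cry1, 0.0229 for Angptl4, 0.0249 for Cry2 and 0.0432 for Bhlhe40. Among lists, the light minus dark contrast gave camera adjusted p = 0.00333 for oxidative phosphorylation (0.000202 to 0.952 over the alternatives), 0.00333 for macrophage markers (3.38e-05 to 0.502) and 0.029 for endothelial markers (0.00914 to 0.478). Single libraries moved these counts: the interaction had 411 genes without KO ZT18 replicate 3 and 964 without WT ZT2 replicate 1. Light minus dark had 68 without KO ZT18 replicate 3, 73 without KO ZT2 replicate 2, 75 without KO ZT18 replicate 1 or WT ZT18 replicate 3, 76 without WT ZT6 replicate 1, and 77 and 78 without KO ZT14 replicates 2 and 3. The rhythm difference had 214 without WT ZT2 replicate 1, 85 without KO ZT2 replicate 2, 80, 85 and 82 without KO ZT18 replicates 1, 2 and 3, and 71 without ZT6. Lists called for light minus dark were 7 without KO ZT10 replicate 1, 6 without WT ZT18 replicate 1 or 2, and 5 without KO ZT6 replicate 1, KO ZT14 replicate 1, WT ZT2 replicate 2, or WT ZT14 replicate 2 or 3.

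Chance was weighed by reassigning labels, drawing 100 assignments with the real one included. With genotypes reassigned within each time, 1 of 100 assignments, the real one, reached 6679 genes in the mean effect (highest other 3106). After the mean genotype difference of each gene was taken out, the real assignment was again the 1 that reached 633 genes for the interaction (highest other 243), 118 for light minus dark (highest other 13) and 128 for the rhythm difference (highest other 5). Times reassigned within a genotype gave at most 1119 rhythmic genes in WT against 4555 and at most 91 in KO-labelled hearts against 3172. Within this draw the real assignment alone reached each count. Libraries were reassigned as if independent, so chance differences between animals stay possible if the libraries of a group share an animal. In the mean effect, mixed assignments also move the real genotype difference into the spread, which lowers their counts. The 6 libraries of a single time make 10 splits, too few for a share under 0.05: the real and the highest other counts were 3529 and 219 at ZT2, 3749 and 0 at ZT6, 3282 and 0 at ZT10, 3645 and 2 at ZT14, and 3780 and 0 at ZT18.

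The breadth of the genotype difference, 6679 of 11790 genes, goes along with deeper KO-labelled libraries. With every library thinned to the same depth 97% of the genes called were called again in the same direction, and with trends on length and GC content removed 88.8% were, so neither depth nor those trends account for the breadth as a whole. Libraries of the genotypes prepared or sequenced apart cannot be told apart from genotype: the first principal component, with 36.3% of the variance, separates the genotypes, and the labels give no batch. An effect of the genotype itself stays open beside it. That genotype includes the MHC transgene, which no group carried alone, so loss of Rev-erb cannot be told apart from the transgene.

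Nr1d1, a Rev-erb gene that the labels do not single out as the target, was higher in KO-labelled libraries. Swapped genotype labels would lower genes that Rev-erb represses, yet all 5 of Arntl, Npas2, Clock, Nfil3 and Cry1 were higher in KO-labelled libraries past the threshold at all 5 times, and 0 libraries lay within the Nr1d1 range of the other genotype, which also argues against single wrong labels. The antisense gene Thra did not rise with it: Thra fell by 15.9 FPKM, 8.2% of the rise of Nr1d1 by 194 FPKM. FPKM are scaled by gene length, so that share is not one of read numbers. Reads of the shared stretch cannot be told apart, so Thra reads counted to Nr1d1 are not excluded. Transcripts of a deleted gene that no longer represses itself are a candidate explanation, and the rhythm of Nr1d1 differed with adjusted p = 1.25e-06, but without values per exon this cannot be told apart from intact transcripts.

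Extracellular matrix genes were higher as a group, with a mean log2 difference of 0.356 ± 0.0267 SE (two-sided permutation p = 2e-05). A smaller share of cardiomyocytes would raise markers of other cell types alike, yet fibroblast markers moved above endothelial markers by 0.179 ± 0.0289 (permutation p = 4e-05); smooth muscle and pericyte markers had a mean of 0.131 ± 0.0197 (p = 7e-05), with 1 of 8 called higher (Acta2) and 1 lower (Abcc9), and macrophage markers 0.0565 ± 0.044 (p = 0.225). More fibroblasts may account for part of the rise, since their 9 markers, all measured in these hearts and led in level by Gsn (472 FPKM in WT) and Dcn (321 FPKM), had a mean difference of 0.123 ± 0.0227 (permutation p = 0.00165), but matrix genes rose above them by 0.233 ± 0.0225 (permutation p = 1e-05, the smallest these permutations give). With trends on length and GC content removed the median of the list was 0.306, 93.2% of its value, with camera adjusted p = 2.01e-06 (3.3e-08 to 0.133 over the alternatives tested with camera, 0.133 with an estimated correlation). Higher matrix transcription in KO-labelled hearts stays a hypothesis, open beside libraries handled apart.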

How the results depend on the processing

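Settings on rebuilt counts, thinning, length and GC content, header numbers and dropped times were chosen after the data were seen; the others were planned. Of results on single genes and lists under the alternatives set in advance, 13493 kept direction and side of the threshold, 115 passed newly, 73 no longer passed and 1 reversed; under added ones the numbers were 1470, 26, 24 and 1. The reversals were light minus dark of oxidative phosphorylation under quantile normalization (adjusted p = 0.925) and of cytosolic ribosomal proteins with length and GC trends removed (0.00493, the lowest of a range up to 0.999).

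For the mean KO minus WT effect edgeR called 7114 genes, 6091 shared with limma and all of the same direction; thinning called 6605 (6479 shared) and the trends removed 6694 (5934 shared). A log2 difference of at least 1 left 128 genes in the mean and 132, 166, 151, 177 and 152 at ZT2, ZT6, ZT10, ZT14 and ZT18, by the construction of a stricter threshold. With the 6 libraries of its own time KO minus WT had 2035 genes at ZT2, 3824 at ZT6, 2875 at ZT10, 2987 at ZT14 and 3489 at ZT18.

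Library weights gave 223 genes for light minus dark, 1418 for the genotype by time interaction and 281 for the rhythm difference. Time as a factor gave 6866 rhythmic genes in WT, 5384 in KO and 633 for the difference, which is then the same test as the interaction. Adjusted p under 0.01 gave 2768 rhythmic genes in WT and 1480 in KO, and an amplitude of at least 0.25 gave 681 and 762. The difference had 79 genes with WT without ZT22, and 171, 71, 154, 151 and 107 with both genotypes without ZT2, ZT6, ZT10, ZT14 and ZT18. Apart from the stricter thresholds, the cause was not tested for these changes or those below.

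Lists called by camera for the mean effect were 11, 14 without a filter, 13 with a mean of at least 5 FPKM, 12 with quantile normalization or trends removed, 0 with an estimated correlation (10 at an unadjusted p under 0.05) and 24 by fry, which tests no contrast with other genes. For light minus dark 3 were called, against 1 with quantile normalization, 5 without a filter, 6 with a pseudocount of 0.1, 5 thinned, 7 with trends removed, 0 with an estimated correlation (2 unadjusted) and 1 by fry.

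Replicate numbers do not pair the samples: 0 of 15 same-numbered pairs within a time correlated over 0.1 (-0.103 to 0.062), and 11 of 33 libraries were closest to their own number. With the replicate block the mean effect had 6633 genes, light minus dark 118, the interaction 582, rhythm in WT 4361, in KO 2973 and the difference 99. The replicate block within ZT gave 6404 genes for the mean, 48 for light minus dark, 225 for the interaction and 6 lists for light minus dark; the replicate block with header numbers gave 6647 genes for the mean and 6 such lists.

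Leaving out each library gave 6522 to 6792 genes in the mean, 2884 to 3558 at ZT2, 3086 to 3942 at ZT6, 2678 to 3469 at ZT10, 3080 to 3830 at ZT14, 3074 to 3978 at ZT18, 68 to 160 for light minus dark, 411 to 964 for the interaction, 4037 to 4552 rhythmic in WT, 2517 to 3475 in KO and 80 to 214 for the difference. Lists ranged from 11 to 12 for the mean and from 2 to 7 for light minus dark. A group left with 2 libraries shares the spread of the others. DESeq2 and its size factors on counts were not run because the deposited unit was FPKM. Depth limits low genes most, and at ZT2 the smallest simulated changes were recovered for 6.2% of genes.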

Other observations

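All tests in this part were chosen after the results of single genes were seen.

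The rise of Cdkn1a raised the hypothesis that genes that respond to p53, a transcription factor induced by DNA damage and other stress, are higher in KO-labelled hearts as a group. It was not supported by the genes left to test. The list was written after the values of 17 of its 29 measured genes had been looked up, so a test of all 29 is no independent test (20 rose and 3 fell, camera adjusted p = 6.15e-05, and 0.000245 with an estimated correlation). Of the 12 genes not looked up before, 6 rose, 2 fell and 4 were not called, with a median log2 difference of 0.102, and the group did not pass (camera adjusted p = 0.293, and adjusted p = 0.484 with an estimated correlation). Among the genes looked up first, Phlda3 went from 6.09 to 20.6 FPKM (1.61 ± 0.04 SE, n = 15 per genotype, limma adjusted p = 1.98e-23), Ephx1 from 28.6 to 89.4 FPKM (1.64 ± 0.04) and Aen from 17.4 to 26.3 FPKM (0.57 ± 0.02), while Sesn1 fell from 60.3 to 40.2 FPKM (-0.55 ± 0.05). Whether p53 is more active in KO-labelled hearts cannot be told from these data.

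Other stress responses were tested in the same way. Of 20 measured genes that respond to NRF2, a regulator of the antioxidant response, 4 had been seen before the list was written. Of the other 16, 10 rose and 3 fell (median 0.122), and the group did not pass (camera adjusted p = 0.463, and 0.587 with an estimated correlation). Of 18 genes that respond to ATF4, a regulator of amino acid stress, 5 had been seen. Of the other 13, 9 rose and 1 fell (median 0.167), and the group did not pass either (camera adjusted p = 0.293, and 0.484 with an estimated correlation). With the genes seen first included, camera adjusted p was 0.108 for NRF2 and 0.0215 for ATF4 (0.273 and 0.16 with an estimated correlation). Among the genes seen first, Nqo1 went from 39.3 to 112 FPKM (1.49 ± 0.03, limma adjusted p = 1.56e-25), Ddit4 from 18.3 to 36.9 FPKM and Mthfd2 from 1.40 to 4.28 FPKM.

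The fatty acid oxidation list had 9 rhythmic members in WT and 2 in KO-labelled hearts, which raised the hypothesis of a weaker rhythm of the list in KO-labelled hearts. The mean of the list had a 24 h amplitude of 0.0591 in WT and 0.049 in KO-labelled hearts on the log2 scale, with peaks at ZT10.8 and ZT10.6, and the curves were not shown to differ (permutation p = 0.927). Permutation p was 0.692 for PPAR-responsive lipid genes, 0.499 for branched-chain amino acid breakdown, 0.309 for oxidative phosphorylation and 0.568 for the matrix genes.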
